A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

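Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark of the start of transcribed genes, was measured by chromatin immunoprecipitation and sequencing in 4 strains of budding yeast. The strains were wild type (WT), a strain lacking both ADA2 and SAS3 (ada2sas3), a strain lacking JHD2 (jhd2) and a strain lacking all 3 genes (ada2sas3jhd2). ADA2 encodes a subunit of the SAGA and ADA histone acetyltransferase complexes, SAS3 the catalytic subunit of the histone H3 acetyltransferase NuA3, and JHD2 the H3K4 demethylase. Per the labels' protocols, cells in mid-log growth were crosslinked with 1% formaldehyde, chromatin was cut to single nucleosomes with micrococcal nuclease, and precipitated DNA was sequenced from both ends. Each genotype had 1 library, and groups came from the genotype labels, except for ada2sas3, whose genotype label spells the strain differently from its title and whose title was used.

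The deposited files hold a signal value, a coverage, for every base of the genome, and the submitters' processing notes name the build sacCer3. The aligner, read filters, treatment of duplicates and scaling are not given in the sources used here. Every deposited signal value in a library was a whole number times 1 factor, to within 0.000188. The factor was 1 for WT, 0.543 for ada2sas3, 0.941 for jhd2 and 1.02 for ada2sas3jhd2, and what it was set on is not given in the sources used here. The mean deposited signal per base, 116, 53.7, 104 and 95.1 in that order, therefore depends on this factor. Dividing it out gave whole-number coverage with means of 116, 99.0, 110 and 93.5. The number of positions at which coverage rose set a lower bound of 8198338, 7237582, 8086280 and 6752533 fragments, and an upper bound of 171, 165, 165 and 167 bp on their mean length. Between 4.50% and 5.59% of bases on the 16 nuclear chromosomes had no coverage. No input or total H3 library was used here, so nucleosome density and the mark were not separated.

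Gene positions came from the RefSeq gene table of assembly R64, whose chromosome lengths match the files, and they hold open reading frames (ORFs) without untranslated regions. Strand was read from the letter W or C of the systematic name. Of 5710 genes with an ORF of at least 300 bp, 5610 were covered in all 4 libraries. Each library was divided by its mean coverage over the nuclear chromosomes without the rDNA array (chromosome XII, 451786 to 468931). The level of a gene is the mean of this scaled signal from 100 bp upstream to 500 bp downstream of the ORF start, ending at the ORF end where that came first, and a level of 1 is the genome mean. A gene was counted as lower or higher when the levels of 2 libraries differed by at least 2-fold and either was at least 1. The 3 deleted genes and the laboratory marker loci were left out of the counts. Positions along genes were compared in fixed windows over ORFs of at least 1400 bp, with 95% intervals from 1000 resamples of genes. Those intervals describe the spread between genes, and intervals on the ratios of single genes are exact binomial intervals on estimated fragments. Neither covers variation between cultures.

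No replicate existed, so no test was run and no p-value is given. There were 34 gene lists, fixed before the data were examined, and 31 of them had at least 5 measured members. The median log2 ratio of each list was placed among 10000 random lists of the same size, matched on 10 groups of WT level, as a description of these libraries. The genes named in 4 comparisons were the 6 lowest and 6 highest ratios among named genes at least 20 kb from a chromosome end and at least 90% covered in at least 1 library. The lowest and highest members of the 5 lists with the most extreme percentiles were named too, as were deleted genes and marker loci. Any other gene is said to have been chosen after its values were seen.

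Alternatives fixed before the data were examined were the values as deposited, scaling to a background poor in the mark (the median over the last 300 bp of ORFs of at least 2000 bp), and a median log2 ratio of 0 over all genes. Others were a window from the ORF start to 300 bp, other level filters, a 1.5-fold threshold, an added 0.1 genome means, other gene sets and random lists matched on ORF length. All scalings shift every gene of a comparison by the same amount, so values relative to the median of all genes do not depend on them. On simulated libraries drawn from the WT coverage at the depth of each library, with 200 of 5710 genes changed, all 33 genes raised 2.5-fold and all 34 lowered to 0.4-fold were counted in the simulated ada2sas3 over WT comparison. None of 33 genes raised 1.5-fold and none of 4338 unchanged genes was counted there, and 10 of 200 unchanged lists lay outside the central 95%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.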

Results

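The series set out to examine H3K4me3 in strains lacking the H3 acetyltransferase subunits Ada2 and Sas3, the demethylase Jhd2, or all 3 proteins. H3K4me3 coverage was available for 1 library each of the WT, ada2sas3, jhd2 and ada2sas3jhd2 genotypes. The median gene window held about 727, 497, 677 and 509 fragments in that order. Because each genotype had 1 library, none of the differences below has a replicate check, and intervals cover counting error or the spread between genes only.

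The deleted genes were examined first. ADA2 (chromosome IV, 1356065 to 1357369) had a mean ORF level of 1.70 genome means in WT and 1.62 in jhd2, against 0.000835 in ada2sas3 and 0.00364 in ada2sas3jhd2. SAS3 (chromosome II, 119379 to 121874) had levels of 0.550 and 0.379 in WT and jhd2, and of 0.00131 and 0.000933 in the ada2sas3 and ada2sas3jhd2 libraries. JHD2 (chromosome X, 644304 to 646490) was at 0.369 in WT and 0.401 in ada2sas3, and at 0.00231 in jhd2 and 0.00137 in ada2sas3jhd2. Each library thus lacked coverage over the genes its label names as deleted. The marker gene HIS3, an enzyme of histidine synthesis, was at 0.00314 in WT and 0.00295 in jhd2 but at 5.64 in ada2sas3 and 5.58 in ada2sas3jhd2, so the libraries without ADA2 and SAS3 also differed from the others at this locus. TRP1 was between 0.0331 and 0.0407 in all 4 libraries. The other marker loci, LYS2, LEU2, HO, CAN1, URA3, MET17, LYP1 and ADE2, lay between 0.336 and 2.75 in all 4.

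Along the gene, H3K4me3 had its highest mean 162 bp downstream of the ORF start in all 4 libraries, at 2.44 genome means in WT, 2.17 in ada2sas3, 2.37 in jhd2 and 2.22 in ada2sas3jhd2. Over 2461 long ORFs, the window from 100 bp before to 200 bp after the ORF start had 3.27 times the signal of the last 300 bp in WT. This ratio was 2.04 in ada2sas3, 2.92 in jhd2 and 2.28 in ada2sas3jhd2, and it does not depend on the scaling of a library.

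**Figure D1:**
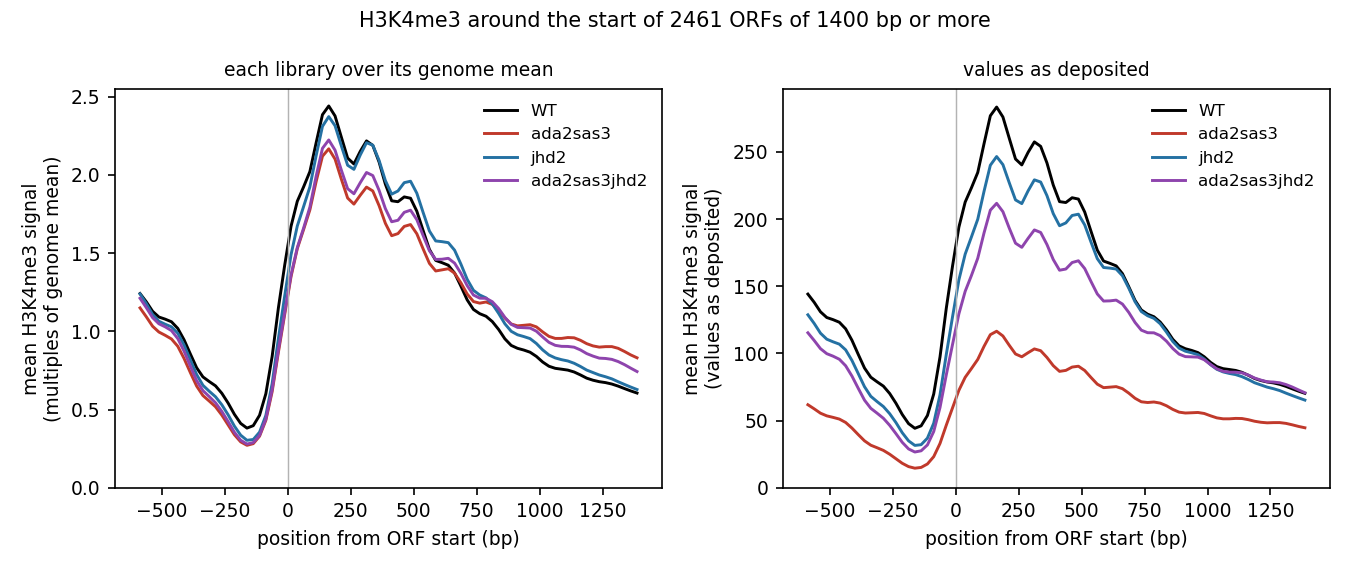
Mean H3K4me3 signal (vertical axes, in multiples of each library's genome mean on the left and as deposited on the right) against distance from the ORF start in bp, in bins of 25 bp, for 2461 ORFs of at least 1400 bp; each line is 1 library. All 4 lines peak 162 bp into the ORF, and in the far part of the gene ada2sas3 lies above WT over the genome mean but below it as deposited.

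How far the mark differed across the genome depended on the scaling. Over 5610 genes the median log2 ratio of ada2sas3 over WT was -0.23 relative to the genome mean, -1.34 as deposited and -0.86 relative to background poor in the mark. For jhd2 over WT the same medians were -0.07, -0.23 and 0.11. They were 0.09, 0.92 and 0.38 for ada2sas3jhd2 over ada2sas3, and -0.09, -0.21 and -0.61 for ada2sas3jhd2 over jhd2. For ada2sas3jhd2 over WT they were -0.17, -0.46 and -0.51. Changes of gene lists are given relative to these medians, which makes them independent of the scaling.

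The comparison of ada2sas3 with WT asks where the mark depends on the 2 acetyltransferase subunits. Genes of the mating pheromone response carried less H3K4me3 in the ada2sas3 library. SST2, which switches off the pheromone G protein, had 5.78-fold less (log2 ratio -2.53, interval -2.84 to -2.23; chromosome XII, 1039270 to 1041366). FAR1, the pheromone-induced inhibitor of cell cycle kinase, had 5.02-fold less (-2.33; chromosome X, 123836 to 126328), and BAR1, the secreted protease that degrades alpha factor, 4.09-fold less (-2.03; chromosome IX, 322342 to 324105). Among named genes at least 20 kb from a chromosome end that passed the filters, SNZ1 of the vitamin B6 pathway had the highest ratio, at 3.21-fold (1.68, interval 1.45 to 1.92; chromosome XIII, 458408 to 459301). In total 296 of 4595 genes were at least 2-fold lower and 20 at least 2-fold higher, against 4000 and 0 as deposited, 1760 and 3 relative to background, and 153 and 42 with the median ratio set to 0.

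**Figure D2:**
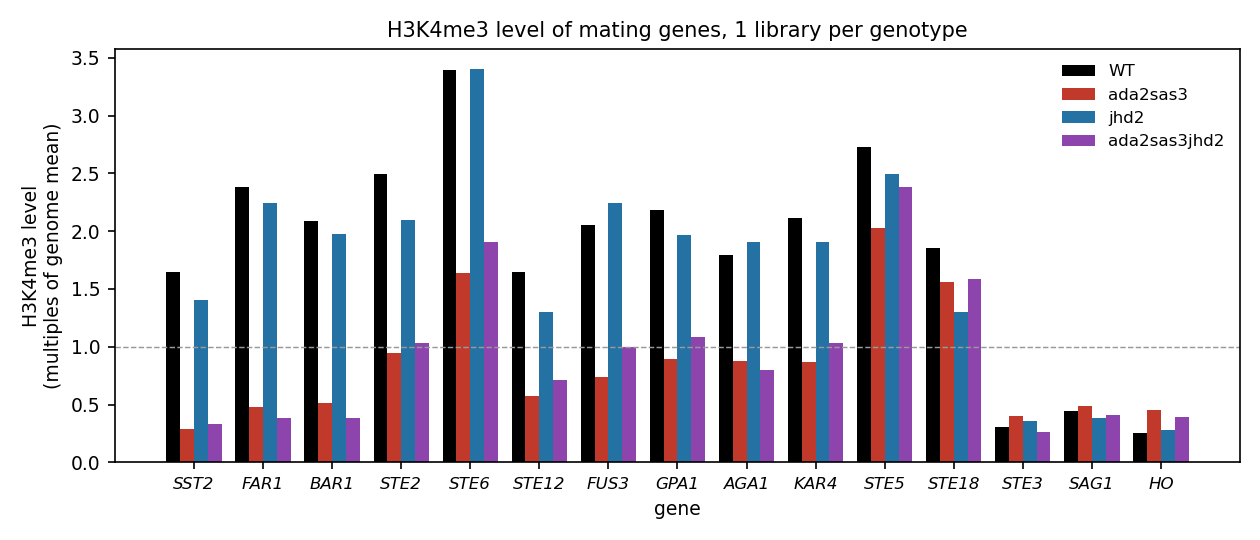
Bars give the H3K4me3 level (vertical axis, multiples of the genome mean, mean from 100 bp upstream to 500 bp downstream of the ORF start) of 15 mating genes in 4 libraries, 1 per genotype; the dashed line marks the genome mean. FAR1 is at 2.38 in WT and 2.24 in jhd2 but at 0.47 in ada2sas3 and 0.38 in ada2sas3jhd2, while STE5 is above 2 in all 4.

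The pheromone response list had 11 of its 17 members at the level filter 2-fold lower in ada2sas3 and none 2-fold higher, and its median lay 0.66 below that of all genes on the log2 scale, lower than all 10000 matched lists. Among members chosen after their values were seen, the transcription factor gene STE12 was at -1.51, the kinase gene FUS3 at -1.47, the receptor gene STE2 at -1.41 and the G protein alpha subunit gene GPA1 at -1.29. PRM2, its highest member, was at 0.81, with a WT level of only 0.19 and a ratio of -0.30 as deposited. Phosphate response genes were 0.35 below all genes (percentile 0), with 5 of 14 members 2-fold lower, from VTC3 of the vacuolar polyphosphate polymerase at -1.56 to the phosphate transporter gene PHO89 at 0.82, which was at -0.29 as deposited. Ergosterol genes were 0.21 below (percentile 0.1), with 5 of 23 members 2-fold lower, although the list was inside the central 95% (percentile 4.17) among random lists matched on ORF length, the lowest member being HMG1, an HMG-CoA reductase chosen after its value was seen, at -1.24. The methionine and sulfate list, 0.12 below all genes, lay within the central range (percentile 7.03).

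Other low genes in ada2sas3 were FOL3, the dihydrofolate synthetase, at -2.16, LRS4 of the monopolin complex at -2.09 and DCN1, a cullin neddylation factor, at -1.77. On the high side were ECM13 at 1.66, GID11 of the GID ubiquitin ligase at 1.53, the cell wall siderophore proteins FIT1 and FIT3 at 1.46 and 1.30, and the allantoate permease gene DAL5 at 1.41. These 5 and SNZ1 remained above 0 as deposited, at between 0.19 and 0.57.

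General stress genes were 0.41 above all genes in ada2sas3 over WT (above all matched lists, but at percentile 92.9 for the 14 members with a level of at least 2), with 24 of 34 members above the median and 1 of 23 members at the level filter 2-fold higher. Their extremes were GAC1, a regulator of glycogen synthesis, at 1.32 and the glycogen synthase gene GSY2 at -0.92. Respiratory chain and ATP synthase genes were 0.31 above (percentile 99.97), from CYC1, cytochrome c, at -0.81 to ATP14, an ATP synthase subunit, at 0.27, which was at -0.84 as deposited and -0.36 relative to background. The seripauperins, a family of cell wall mannoproteins at chromosome ends, were 1.34 above (above all matched lists, which were themselves 0.56 above), with 16 of 17 members above the median and PAU10 at 1.72. PAU6 was at -0.83 with an interval of -2.72 to 0.86, and only 27.4% of its window was covered in the least covered library. Sequence shared within this family may limit the values, which was not tested. Also above all genes were cytosolic ribosomal proteins (0.16, percentile 99.9), proteasome subunits (0.24, 99.4), histones (0.28, 99.3), cell wall genes (0.24, 98.5), amino acid synthesis (0.23, 98.4) and flocculins (1.31, 97.8). Several of these were inside the central 95% under another setting: ribosomal proteins (0.07, percentile 43.4) and amino acid synthesis (95.1) in the window from the ORF start to 300 bp, histones (87.9) against lists matched on ORF length, and cell wall genes (60.1) and proteasome subunits (96.9) at a level of at least 2. In all, 12 of 31 lists lay outside the central 95%, and 5 of the 12 did so in every alternative run that they entered. Seripauperins and flocculins, among these 5, had too few members with a level of at least 2 to enter that run. None of the 5 flocculins passed the level filter, and their matched lists were themselves 0.75 above all genes. If genes varied independently of each other, 1.55 of the 31 lists would lie outside. The other comparisons had between 10 and 15 lists outside, also where no gene was 2-fold apart, so the excess over 1.55 does not measure an effect of genotype. As deposited, with the shift of the whole library included, the medians of the respiratory and stress lists were -1.03 and -0.93.

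**Figure D3:**
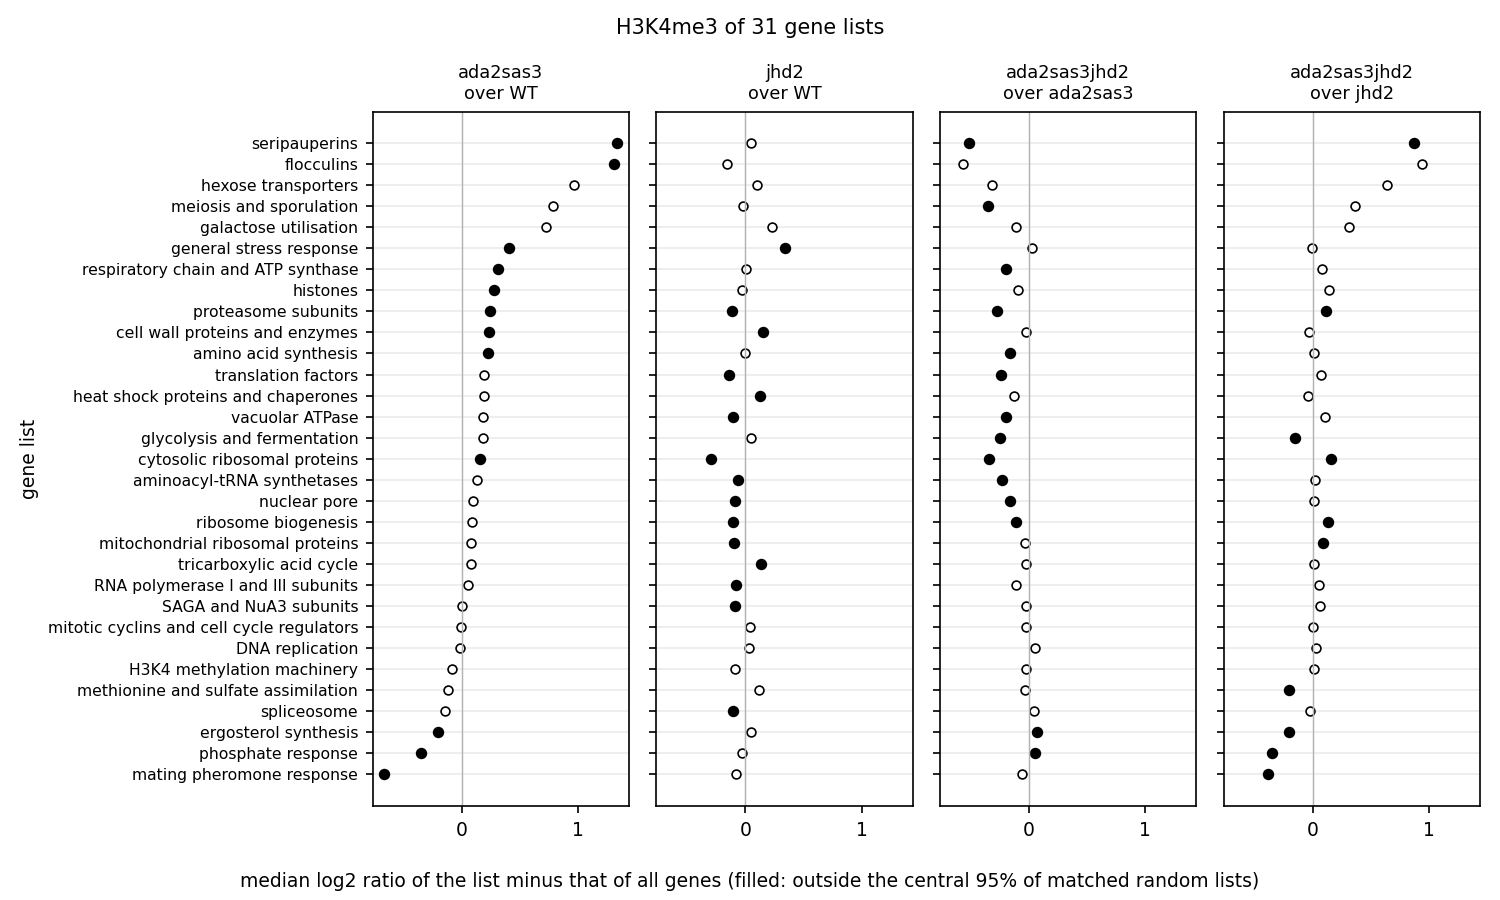
Each point is the median log2 H3K4me3 ratio of 1 of 31 gene lists minus the median of all genes (horizontal axis), for 4 comparisons of 2 libraries each; filled points lie outside the central 95% of matched random lists. Mating pheromone genes are lowest in ada2sas3 over WT at -0.66, and cytosolic ribosomal protein genes are lowest in jhd2 over WT at -0.29.

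By position, the ada2sas3 library differed from WT with opposite sign at the ends of long genes. Its log2 ratio was -0.24 around the ORF start and 0.44 over the last 300 bp, the latter turning to -0.67 as deposited and -0.19 relative to background. The difference between those 2 windows, -0.68 (interval over genes -0.71 to -0.65), is free of the scaling. Over 5 groups of genes from the lowest to the highest WT level, the median ratios were 0.09, -0.56, -0.36, -0.20 and -0.00, so they had no single trend with level, and all 5 were below 0 as deposited.

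The comparison of jhd2 with WT asks what loss of the demethylase alone does to the mark. Differences were small at single genes, and cytosolic ribosomal protein genes had lower ratios than most other genes. Of 129 cytosolic ribosomal protein genes, 127 lay below the median of all genes, and their median was 0.29 below it (lower than all matched lists). RPL31A, their lowest member, was at -0.90, RPL33A at -0.88 (1.84-fold lower, interval -1.08 to -0.68; chromosome XVI, 282122 to 282970) and RPS13 at -0.80, while RPP2B was at -0.00 (0.18 relative to background). Among named genes at least 20 kb from a chromosome end that passed the filters, the cell wall protein gene SPI1 was highest at 0.89 (1.85-fold, interval 0.67 to 1.10; chromosome V, 468370 to 468816). At the level filter 1 of 4616 genes was 2-fold apart, the uncharacterised YIR042C at 1.28, which lies near a chromosome end and was chosen after its value was seen. As deposited 2 genes were lower and 1 higher, and relative to background none was lower and 7 were higher. In the window from the ORF start to 300 bp 4 genes were lower and 1 higher, and without a level filter 14 were lower and 7 higher.

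Other genes with low ratios in jhd2 were the glucosyltransferase gene DIE2 at -0.83, the mitochondrial RNA factor CCM1 at -0.81, VPS52 of the Golgi tethering complex GARP at -0.79 and the ribosome assembly factor CIC1 at -0.74. High ratios were found at the yapsin protease YPS3 (0.88), the membrane protein FMP45 (0.86), the zinc transporter ZRT1 (0.83), the mannoprotein TIR1 (0.79) and the thiamine transporter THI7 (0.77). These directions also held as deposited, between -0.99 and -0.90 for the low genes and between 0.61 and 0.72 for the high ones.

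General stress genes were 0.34 above all genes in jhd2 (above all matched lists), with 32 of 34 members above the median, from TRX2, a thioredoxin, at -0.23 to NQM1, a transaldolase, at 0.88. Cell wall genes (0.15, percentile 99.6), tricarboxylic acid cycle genes (0.13, 99.6) and heat shock genes (0.13, 98.9) were above as well. Below lay translation factors (-0.14, percentile 0), with EFB1 at -0.50 and CAM1 at 0.10 (-0.06 as deposited), proteasome subunits (-0.11, percentile 0), from RPN9 at -0.58 to PRE6 at 0.01 (-0.15 as deposited), and ribosome biogenesis (-0.10, percentile 0), from the helicase gene DBP9 at -0.66 to NOP1 at 0.08 (-0.08 as deposited). Mitochondrial ribosomal proteins (-0.10), tRNA synthetases (-0.06), the nuclear pore (-0.09), the vacuolar ATPase (-0.10), the spliceosome (-0.11), RNA polymerase I and III (-0.08) and SAGA and NuA3 subunits (-0.09) had percentiles between 0.04 and 1.52. Heat shock genes (percentile 88.4) and the nuclear pore (17.4) were inside the central 95% in the window from the ORF start to 300 bp, the spliceosome (52.5) and cell wall genes (95.2) at a level of at least 2, and tRNA synthetases (13.0), RNA polymerases (10.5), the vacuolar ATPase (5.63) and SAGA and NuA3 subunits (4.36) against lists matched on ORF length. In all 15 of 31 lists lay outside the central 95%, and 7 of the 15 did so in every alternative run. Mating pheromone genes, at -0.08, did not (percentile 7.57).

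By position, jhd2 over WT was -0.11 around the ORF start and 0.13 in both windows of 300 bp that begin at 500 and 800 bp, with 0.05 over the last 300 bp. These signs turned under other scalings, the start window to 0.07 relative to background and the other 3 to between -0.11 and -0.03 as deposited. The scaling-free difference between start and end was -0.16 (interval over genes -0.18 to -0.15), against -0.053 as a median of per-gene ratios and -0.10 in ORFs of at least 2500 bp.

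The comparison of ada2sas3jhd2 with ada2sas3 asks whether loss of the demethylase alters the mark when both acetyltransferase subunits are absent. Most genes that were low in ada2sas3 had higher levels in the strain that also lacked JHD2, but 2 of the 3 pheromone genes with the lowest ratios did not. Of the 296 genes 2-fold lower in ada2sas3, 283 were higher in ada2sas3jhd2 than in ada2sas3. Their median log2 ratio was 0.33, where all genes had 0.09. The value for all genes is not matched on level, and 46 of the 296 genes had a level of at least 2. Over 5 groups of all genes from the lowest to the highest WT level, the medians were 0.02, 0.20, 0.14, 0.08 and -0.02. Part of the excess over 0.09 may thus go with WT level, and no level-matched value was calculated. Against WT the median of the 296 genes was -1.24 in ada2sas3 and -0.93 in ada2sas3jhd2, and 178 of them (60.1%) were no longer 2-fold lower. Since these genes were picked for a low ada2sas3 value, some return is built in: counting noise alone, simulated 100 times, gave a median of 26 and at most 37 genes, which leaves out variation between cultures. FAR1 and BAR1 were lower still, at -0.31 (interval -0.65 to 0.03) and -0.43 (interval -0.76 to -0.09), or 0.52 and 0.40 as deposited. SST2 was at 0.20 (interval -0.21 to 0.60). The intervals of FAR1 and SST2, which cover counting error only, thus include 0. Levels of FAR1, BAR1 and SST2 were 0.47, 0.51 and 0.29 in ada2sas3, below its background poor in the mark (0.55). In ada2sas3jhd2 they were 0.38, 0.38 and 0.33, again below its background (0.45). Relative to background the ratios were -0.02, -0.14 and 0.49. The lower values of FAR1 and BAR1 thus cannot be told apart from a fall in background. The pheromone list as a whole was 0.06 below all genes (percentile 21.7), with 13 of 23 members below the median. Other scalings shift all of these ratios together, as deposited by 0.82 and relative to background by 0.29, and so set how many low genes return.

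No gene of 4040 was 2-fold apart between ada2sas3jhd2 and ada2sas3, while 1284 were 2-fold higher as deposited and 2 relative to background. Under the same filters and distance from chromosome ends, the highest ratios were at PCD1, a peroxisomal pyrophosphatase (0.89, 1.86-fold, interval 0.64 to 1.15; chromosome XII, 441715 to 442737), the glycosylation gene ALG14 (0.78), the bud neck kinase KCC4 (0.66), the nuclease subunit SLX4 (0.65), SHH4 (0.64) and the histone N-terminal acetyltransferase NAT4 (0.64). PCD1, SLX4 and SHH4 lie on chromosome XII, whose signal in 20 kb bins was higher in ada2sas3jhd2 by a median factor of 1.04 over ada2sas3 and 1.07 over jhd2, the highest of the 16 chromosomes in both. The lowest were at the glycolytic enzyme TDH3 (-0.60, 1.52-fold, interval -0.80 to -0.41; chromosome VII, 882812 to 883810), the aldehyde dehydrogenase ALD6 (-0.54), the leucine synthesis enzyme LEU1 (-0.52), RPS13 (-0.52), the oxaloacetate carrier OAC1 (-0.49) and RPL27A (-0.49), and all 6 of these were above 0 as deposited, at between 0.22 and 0.33.

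Cytosolic ribosomal protein genes were 0.35 below all genes in this comparison too, with 129 of 129 members below the median (lower than all matched lists), although their own median of -0.25 was 0.57 as deposited. All 32 proteasome genes and all 28 translation factor genes were below the median, by 0.27 and 0.24 (percentile 0 each), with RPN2 lowest at -0.36, PRE9 highest at -0.01, and GCD11 and TEF1 at -0.29 and -0.03. Seripauperins were 0.52 below (percentile 0), from PAU15 at -0.96 to PAU2 at -0.15, and respiratory genes 0.20 below (percentile 0.02), from ATP2 at -0.33 to QCR6 at 0.31. Of the genes named here with ratios below 0, PAU15 stayed below 0 as deposited, at -0.14, while RPN2, PRE9, GCD11, TEF1, PAU2 and ATP2 were above 0, at between 0.47 and 0.81. TEF1 shares its sequence with TEF2, and 58.2% of its window was covered in the least covered library. Ergosterol genes (0.07 above all genes, percentile 98.1) and phosphate genes (0.05, 98.8) were the lists on the high side among the 14 outside the central 95%, but against lists matched on ORF length both were inside it (89.7 and 83.4). The scaling-free difference between the start and the end of long genes was 0.16 (interval over genes 0.14 to 0.18).

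The comparison of ada2sas3jhd2 with jhd2 repeats the loss of ADA2 and SAS3 in cells without the demethylase, and shares no library with ada2sas3 over WT. Under the same filters and distance from chromosome ends, the lowest ratios were those of pheromone genes: FAR1 at -2.55 (interval -2.82 to -2.28), BAR1 at -2.38 and SST2 at -2.10. SNZ1 was highest at 1.82 (interval 1.59 to 2.06), followed by ARG80, a regulator of arginine genes, at 1.52 (chromosome XIII, 352603 to 353136), GID11 at 1.48 and ECM13 at 1.48. In total 92 of 4459 genes were 2-fold lower and 10 higher, against 493 and 1 relative to background and 138 and 9 as deposited. Across 4682 genes the 2 sets of log2 ratios had a Pearson correlation of 0.81 and a Spearman correlation of 0.76, with genes not being independent replicates. Of genes counted in both comparisons, 70 were 2-fold lower in both where independent lists would share 4.39, and 7 were higher in both where 0.0288 would be shared. The 2 sets of ratios for loss of JHD2, jhd2 over WT and ada2sas3jhd2 over ada2sas3, which share no library either, correlated less, at a Pearson correlation of 0.24 and a Spearman correlation of 0.23. After a fitted line and the trend with level were taken off, these were 0.41 and 0.44, against 0.79 and 0.73 for loss of ADA2 and SAS3.

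The spread of the ratios was smaller in the comparison without JHD2, with an SD over genes of 0.32 against 0.44, and a slope of 0.60 of the second set on the first. Noise in the first set lowers such a slope as well. The background poor in the mark was also highest in ada2sas3, at 0.55 genome means against 0.45 in ada2sas3jhd2, and the cause of the smaller spread was not tested. Further low genes in ada2sas3jhd2 over jhd2 were YRO2, a membrane protein related to a heat shock protein, at -1.71, LRS4 at -1.68 and the mitochondrial glutamyl-tRNA synthetase MSE1 at -1.62. ANB1, the translation factor made without oxygen, was at 1.16 and the mannoprotein TIR3 at 1.14. All of these kept their sign as deposited.

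Pheromone genes were 0.39 below all genes (lower than all matched lists), with 6 of 17 members 2-fold lower, phosphate genes 0.35 below (percentile 0), from PHO12, an acid phosphatase with 65.7% of its window covered in the least covered library, at -1.04 to PHO87 at 0.52 (-0.00 relative to background), and ergosterol genes 0.20 below (percentile 0.01). Glycolysis (-0.15, percentile 0.02, but 3.68 against lists matched on ORF length) and methionine genes (-0.20, percentile 0.41) were low as well. On the high side were ribosomal protein genes (0.16, percentile 100), from RPL27A at -0.39 to RPS31 at 0.63, ribosome biogenesis (0.13, percentile 100), from PWP2 at -0.21 to DBP9 at 0.44 (-0.08 relative to background), and seripauperins (0.87, percentile 100), with PAU11 at 1.69 and PAU6 at -0.06. PRM3, a pheromone-regulated membrane protein, was the highest pheromone gene at 0.61. The scaling-free difference between the start and the end of genes was -0.36 (interval over genes -0.39 to -0.33), smaller in size than the -0.68 of ada2sas3 over WT.

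**Figure D4:**
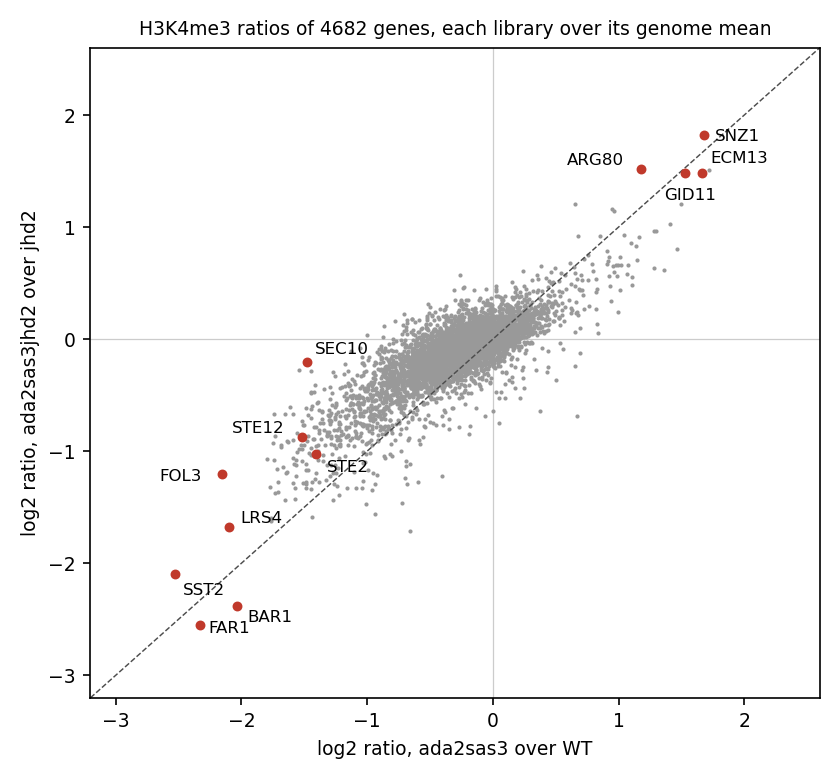
Each point is 1 of 4682 genes, with its log2 H3K4me3 ratio of ada2sas3 over WT on the horizontal axis and of ada2sas3jhd2 over jhd2 on the vertical axis, each library over its genome mean; the dashed line marks equal ratios and red points are named genes. FAR1 lies at -2.33 and -2.55 and SEC10 at -1.48 and -0.21; another scaling would move all points together.

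The design also asks whether the deletions add up. The log2 ratio of ada2sas3 over WT differed by at least 2-fold from that of ada2sas3jhd2 over jhd2 at 11 of 4682 genes, all of which were chosen by this size and none of which was tested. Over all 4682 genes the median difference was -0.15 (-0.26 relative to background and -1.135 as deposited). This shift of all genes favours differences below 0, and no count centred on that median is given. At 8 genes the loss of ADA2 and SAS3 lowered the level more with JHD2 present: the exocyst gene SEC10 (-1.48 against -0.21), the prefoldin gene PFD1 (-1.54 against -0.27), the TFIIH kinase KIN28 (-1.44 against -0.29), RIT1 (-1.74 against -0.67), VPS52 (a difference of -1.04), the repair gene RAD34 (-1.12 against -0.10), the lariat debranching enzyme DBR1 (-1.42 against -0.40) and IPA1 (-1.61 against -0.60). At 3 it was the other way: the acetate transporter ADY2 (0.38 against -0.64), YRO2 (-0.66 against -1.71) and YIR042C (0.67 against -0.69). As deposited the ratios over WT of ADY2 and YIR042C were -0.73 and -0.44, so their opposite signs depend on the scaling. The number was 0 among genes with a level of at least 2 in any library and 3 with 0.1 genome means added to each level, but 34 in the window from the ORF start to 300 bp, with 31 of the first kind and 3 of the second. It also depended on the scaling, being 24 relative to background, with 23 of the first kind, and 3377 as deposited, all of the first kind.

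Genes at chromosome ends were taken as a separate group. The 79 genes within 10 kb of an end had a median ratio of 0.67 in ada2sas3 over WT (-0.44 as deposited). This was 0.90 above all genes and above all lists matched on WT level, whose own median was 0.25. In ada2sas3jhd2 over jhd2 the median was 0.33 (percentile 99.91), and in jhd2 over WT 0.09 (percentile 97.94; -0.07 as deposited), but the 39 of these genes covered at every base were inside the central 95% in both, at percentiles 95.01 and 65.53. In ada2sas3jhd2 over ada2sas3 it was -0.20 (percentile 0.03; 0.63 as deposited). The 111 genes at 10 to 20 kb were at 0.19 in jhd2 over WT (percentile 100; 0.03 as deposited), and the 75 of them covered at every base at 0.21 (percentile 100). These 75 were at -0.19 in ada2sas3jhd2 over jhd2 (percentile 0.28), below rather than above matched lists, where all 111 were inside the central 95% (percentile 42.5). In ada2sas3 over WT the 111 were inside it too (percentile 90.3).

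The ada2sas3jhd2 library was also set against WT. There 123 of 4618 genes were 2-fold lower and 37 higher, against 328 and 17 as deposited, 408 and 12 relative to background, and 60 and 52 with the median ratio set to 0. Relative to all genes, pheromone genes (-0.70, percentile 0) and ribosomal protein genes (-0.17, percentile 0) were lowest, and general stress genes (0.43, percentile 100) and seripauperins (0.91, percentile 99.95) highest in percentile. The scaling-free difference between start and end of genes was -0.52 (interval over genes -0.55 to -0.50).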

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

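The test of the correlation between residuals, the line test in the strains without JHD2, the look at the upstream window and both mating tests were chosen after the result was seen, and coarse profiles, medians at chromosome ends and list percentiles had been looked at before the other tests were written.

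The ratio on loss of ADA2 and SAS3 had opposite signs with and without JHD2, each past a set minimum size, at 4 of the named genes: ADY2 (0.38 over WT, -0.64 over jhd2), NQM1 (0.36, -0.62), STE3 (0.39, -0.47) and YIR042C (0.67, -0.69). The difference was not tested, as each genotype had 1 library. STE3 (levels from 0.26 to 0.40) and NQM1 (0.38 to 0.69) were below the genome mean in all 4 libraries and so failed the level filter. ADY2 and YIR042C had been chosen for the size of this same difference, so their opposite signs are no separate finding. As deposited the ratios over WT of ADY2, STE3 and YIR042C were -0.73, -0.72 and -0.44, and that of NQM1 was below 0 too, so the opposite signs depend on the scaling.

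The first pattern is the weaker contrast between the start and end of genes in ada2sas3, with its gene-to-gene differences, where an even background from lower enrichment would place windows on a line between libraries; among the second, the third and the fourth windows the largest departure was 0.13 genome means for ada2sas3 on WT and 0.038 for ada2sas3jhd2 on jhd2. The first value passed the bound of 0.1 set beforehand, but jhd2, which has both acetyltransferase subunits, departed from its line on WT by 0.18 in the same window, so that bound was judged wrong after the result was seen. The upstream window, not part of that test, departed further, by -0.25 for ada2sas3 on WT and -0.12 for ada2sas3jhd2 on jhd2 against -0.061 for jhd2 on WT, which argues against a background equal at every base but leaves open one carried by nucleosomes, whose density in that window was not measured. A line was fitted with a background of at least 0, which came to 0, after a free fit gave a negative one (-0.68). The spread of genes around it was 4.73 times counting noise, which decides nothing with single cultures. The residuals of ada2sas3 over WT and of ada2sas3jhd2 over jhd2, which share no library, correlated at 0.79 across genes. In 100 shuffles of genes the largest value was 0.044. Shuffling removes any property of a gene that libraries share, so that value adds no weight against a background. The correlation of 0.79 itself argues against an even background alone, although the bound of 0.3 was set with the uncorrected correlation known. The residuals of jhd2 over WT and of ada2sas3jhd2 over ada2sas3 passed that bound too, at 0.41, so passing it is not particular to loss of ADA2 and SAS3. A background that follows nucleosome density, with no input library used here, stays open beside an effect of ADA2 and SAS3. So does strain construction, as the libraries lacking ADA2 and SAS3 also differ from the others at HIS3.

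The second pattern is the low level of pheromone genes in both libraries lacking ADA2 and SAS3. Cells of the other mating type would have STE6 near a silent level and STE3 marked, but the lower STE6 level was 1.64 genome means and STE3 was at 0.40 and 0.26, although BAR1, silent in such cells as well, was at 0.51 and 0.38. Diploid cells would lose haploid-specific genes, of which STE18 (lower level 1.56) and STE5 (2.02) stayed marked while FAR1 (0.38), FUS3 (0.74) and GPA1 (0.89) were low. As these genes point both ways and were picked after their values were seen, diploid cells in the cultures cannot be told apart from the other explanations. Culture state and strain construction were not tested and stay open beside the genotype.

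The third pattern is the higher ratio of genes within 10 kb of chromosome ends in ada2sas3 over WT. A background lifting all weakly marked genes would lift matched genes alike, but the percentile among lists matched on WT level was 100. The 39 genes covered at every base had a percentile of 100 too. Full coverage sets a gene apart from repeated families only if reads mapping to several places were dropped. As the read filters are not given, this result cannot exclude shared reads. In ada2sas3jhd2 over jhd2 those 39 genes were at percentile 95.01, inside the central 95%. With 1 library per genotype, a library difference stays open beside the genotype, as do background and shared reads.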

How the results depend on the processing

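The removal of a fitted even-background line before counting and the as-deposited count of non-additive genes were chosen after seeing the data. All other alternatives were fixed before. No paired analysis by replicate was possible because each genotype had 1 library, and a fit of additive effects over the 4 libraries, with 1 residual degree of freedom, was not run. Apart from changes fixed by construction (a scaling shifts all genes alike, a filter or threshold alters which genes count), the cause was not tested.

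Counts of genes at least 2-fold apart are given in the order ada2sas3 over WT, jhd2 over WT, ada2sas3jhd2 over ada2sas3, ada2sas3jhd2 over jhd2 and ada2sas3jhd2 over WT, and were 316, 1, 0, 102 and 160. Relative to background they were 1763, 7, 2, 494 and 420, and at 1.5-fold 1069, 79, 15, 390 and 642. Without a level filter they were 521, 21, 12, 223 and 295. As deposited they were 4000, 3, 1284 and 345, leaving out ada2sas3jhd2 over jhd2, which stayed within 1.5 times. With a level of at least 2 they were 49, 0, 22 and 28, leaving out ada2sas3jhd2 over ada2sas3. With the median set to 0, ada2sas3 over WT had 195. For jhd2 over WT, leaving out chromosome ends gave 0, and the window from the ORF start to 300 bp gave 5, with 4 lower where the main count had 1 higher. With a fitted even-background line removed, ada2sas3 over WT had 249. That line had a background of 0 and a slope of 0.926, so no background was subtracted and this count reflects a rescaling only.

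The difference between the start and the end of genes, in the same order, was -0.86, -0.053, 0.28, -0.53 and -0.58 as a median of per-gene ratios, and -0.78, -0.10, 0.22, -0.45 and -0.56 in ORFs of at least 2500 bp. Without divergent starts it was -0.18 in jhd2 over WT and 0.14 in ada2sas3jhd2 over ada2sas3. All signs stayed. Non-additive genes numbered 11, and 24 relative to background, 34 in the window to 300 bp, 0 at a level of at least 2, 3 with 0.1 genome means added and 3377 as deposited.

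Single windows in the first 4 of these comparisons changed sign as follows. As deposited, ada2sas3 over WT was -0.87 in the fourth window and -0.67 in the last, jhd2 over WT -0.15, -0.032, -0.026 and -0.11 in the second to the last, ada2sas3jhd2 over ada2sas3 0.80 in the fourth and 0.69 in the last, and ada2sas3jhd2 over jhd2 -0.040 in the fourth. Relative to background, ada2sas3 over WT was -0.38 in the fourth and -0.19 in the last, jhd2 over WT 0.048 upstream and 0.069 in the first, ada2sas3jhd2 over ada2sas3 0.26 in the fourth and 0.15 in the last, and ada2sas3jhd2 over jhd2 -0.44 in the fourth and -0.27 in the last. With the median set to 0, ada2sas3 over WT was 0.047 in the second and 0.21 in the third, ada2sas3jhd2 over ada2sas3 -0.022 upstream, -0.069 in the first, -0.026 in the second and -0.028 in the third, and ada2sas3jhd2 over jhd2 0.0095 upstream and 0.0030 in the third. For jhd2 over WT the second and last windows were -0.020 and -0.079 as medians of per-gene ratios, and -0.018 and -0.021 in ORFs of at least 2500 bp.

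For ada2sas3jhd2 over WT windows were compared under 2 other scalings alone: the third and the fourth were -0.24 and -0.066 as deposited, against 0.045 and 0.22, and relative to background the third, the fourth and the last were -0.30, -0.12 and -0.038, the last against 0.31.

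Of 144 alternative values for single windows in those 4 comparisons 28 stayed within their interval over genes, 87 moved without changing sign beyond it and 29 changed sign. Of 1020 alternative values for named genes 824 kept their direction and side of the 2-fold threshold, 196 did not, and none of the genes past that threshold changed sign. The numbers of lists outside the central 95% stayed within 1.5 times under each alternative run, but which lists these were changed. In the order of comparisons above, 5 of 12, 7 of 15, 11 of 14, 7 of 10 and 4 of 10 were outside it on the same side in every alternative run that they entered. At a level of at least 2, 26 of the 31 lists had enough members. Lists without enough, such as seripauperins and flocculins, were judged on the other runs. Deleted genes stayed at or below 0.364% of the genome mean, or 0.304% relative to ORFs of the same chromosome. With 497 fragments in the median gene window of ada2sas3 and 509 in that of ada2sas3jhd2, log2 ratios of unchanged genes had an SD between 0.0720 and 0.0802 in simulated data. No unchanged gene was counted at 2-fold there, and no change between 1.5-fold and 2.5-fold was simulated. Depth limits weakly marked genes and genes near the 2-fold line, across which counting noise alone moved a median of 26 of the 296 genes lower in ada2sas3.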

Other observations

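No test was run on the values that follow. The silent cassette genes HMLALPHA1, HMLALPHA2 and HMRA2 were at 0 or nearly so in all 4 libraries, while HMRA1 was between 0.362 and 0.677 genome means. The cassettes share sequence with the mating type locus, and which locus the HMRA1 signal came from was not examined. The rDNA array, left out of the library means, was at 0.167 genome means in WT, 0.203 in ada2sas3, 0.142 in jhd2 and 0.193 in ada2sas3jhd2. The mitochondrial chromosome was listed at 0 throughout.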
